A study of Mus musculus with 4 samples.

How the data were processed

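The series holds 4 single-colour arrays of mouse placenta, 2 from wild-type and 2 from STOX1-overexpressing animals of the FVB/N strain at day 16.5 of gestation. Per the labels, placentas were freed of fetal membranes, each sample is a pool of placentas, total RNA was extracted with TRIzol, and the RNA was labelled with Cy3. How many placentas, litters or mothers went into a pool, and whether the pools shared any, is not given in the sources used here. The p-values of single features therefore measure only the spread between these pools, which may be partly technical. Those of the camera list test at a preset correlation set a list's genes against other genes. Their error is the spread among genes under an assumed correlation, not the spread between pools.

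The deposited table holds log2 expression values for 25631 features, which the authors made with RMA, per the submitters' processing notes. Those notes give no version, and the array platform, the scanner and the annotation are not given in the sources used here. Values ran from 2.63 to 15.74, and the array medians lay between 7.90 and 7.95. Group and pool number came from the sample titles. All 4 columns were used as deposited, with no pseudocount and no filter on dim features. No measure of background was used, so whether a dim feature lay above background is unknown. RMA sets the arrays to nearly the same distribution, so a shift shared by most genes would not be seen.

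Features carry RefSeq transcript accessions. They were named through a RefSeq gene table of assembly GRCm38.p6, with versions removed on both sides, and no coordinates were taken from it because the array's own build is unknown. Of the 25631 features 17780 received a symbol, including 17761 of 18879 curated transcripts and 19 of 6752 predicted transcripts, while 7851 stayed unnamed. The named features cover 17277 genes, of which 433 have more than 1 feature, and the feature with the highest mean over the 4 arrays then stood for the gene. Stox1 and Xist matched 0 features and are not analysed here.

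Single features were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at the default prior, for STOX1 minus wild-type over all 4 arrays, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The prior had 1.80 degrees of freedom, which with 2 residual degrees of freedom gave 3.80 in all. An SE is limma's moderated standard error of the log2 difference, an SD is taken over the 2 arrays of a group, and a fold is 2 to the power of the log2 difference.

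Before the data were examined, 45 gene lists were fixed. The process lists were: angiogenic factors and receptors, genes raised in human preeclamptic placenta, nitric oxide pathway, antioxidant and Nrf2 targets, oxidative phosphorylation, mitochondrial biogenesis, HIF targets, glycolysis, renin-angiotensin system, proinflammatory cytokines and NF-kB targets, interferon-stimulated genes, complement, unfolded protein response, heat shock, immediate early genes, cell cycle, p53 targets and apoptosis, extracellular matrix, matrix proteases, coagulation, steroid synthesis, cholesterol synthesis, nutrient transport, insulin-like growth factors, imprinted genes, adhesion, Wnt, TGF-beta, ribosomal proteins, and olfactory with vomeronasal receptors. The cell type lists were: prolactin family, spongiotrophoblast, cathepsins, glycogen cells, syncytiotrophoblast, trophoblast progenitors, endothelium, pericytes and smooth muscle, decidual stroma, erythroid cells, macrophages, natural killer cells and lymphocytes, neutrophils, yolk sac, and sex-linked genes. Of 1053 list entries, with a symbol counted once for each list it stands in, 1014 were measured. The sex-linked list had 4 measured genes, under the minimum of 5, so 44 lists were tested.

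Lists were tested against the other named genes with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move together without setting them against other genes. Counts of genes whose arrays do not overlap are set beside the share expected by chance for 2 against 2 arrays, 16.7% in each direction.

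Named genes followed a rule set at the same time. Stox1, Stox2 and 9 genes of the STOX1 and pre-eclampsia literature are always given. The 15 largest rises and 15 largest falls that pass are given, filled up to 10 each from genes with an unadjusted p under 0.01 where too few pass, leaving out genes known only by a clone or predicted number. Each called list gives the 4 members with the smallest unadjusted p in its direction, and 16 other lists give 2. Members of a list that went against its direction, F5, Cfi, Alb and the Y-linked genes were added after their values were seen.

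The scripts were tested on simulated data drawn from the fitted spread. For features the recovery is given beside the comparison, with 4 false calls among 25631 features. A shift of 0.3 log2 units in the interferon list was called in 91 of 100 simulated sets of 17277 independent genes, and 0 lists were called without a shift. These counts do not cover lists whose genes move together, as real ones can. Random lists for the closing section were 10000 draws matched to each gene by mean expression, from the 50 nearest genes on either side, and genes as bright as those low in wild-type pool 2 were the same number of neighbours by mean over the other 3 arrays.

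Alternatives planned in advance were quantile normalization, median centring, leaving out the lowest 25% or the lower 50% of features, an intensity trend with a robust prior, a plain equal-variance test, the replicate number as a block, leaving out each array, the mean of a gene's features, an estimated correlation and fry. Other backgrounds for the list test, a crossed block and a test of named genes alone were chosen after seeing the data. With 1 array of a group left out, the lone array is assumed to vary like the other group. A pseudocount alternative was planned only for linear values and was not run, since the values are logarithmic.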

Results

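Placental gene expression was measured in mice overexpressing STOX1 and in wild-type mice, all of the FVB/N strain, at day 16.5 of gestation. STOX1, storkhead box 1, is a winged-helix transcription factor studied for its association with pre-eclampsia, the hypertensive disorder of pregnancy. Each group had 2 samples, each a pool of placentas hybridised to its own single-colour array, and each array gave a log2 expression value for 25631 transcript features. The array medians were 7.95 and 7.90 in the wild-type pools and 7.94 and 7.93 in the STOX1 pools. The small number of arrays limits the precision of every value that follows.

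Across features, the STOX1 pools resembled each other most (Pearson r = 0.986 over the 25631 features of the pair), and the wild-type pools resembled each other least (r = 0.976). The other 4 pairs, each of a STOX1 and a wild-type pool, had r from 0.977 to 0.982. Between the wild-type pools 2438 features lay more than 2-fold apart, against 1493 between the STOX1 pools. The pairs of a STOX1 and a wild-type pool had 1768 to 2574, so by this count the wild-type pair was not the furthest apart. Features are not independent replicates, so these correlations describe the arrays only. By r, the wild-type pools lay at least as far from each other as from the STOX1 pools.

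The targeted gene comes first in a design of this kind, but 0 features matched Stox1, and the overexpression itself is not analysed here. Its paralogue Stox2 stood at 8.84 ± 0.39 in STOX1 pools and 8.36 ± 0.025 in wild-type pools (mean log2 value ± SD, n = 2 each). Ctnna3, which encodes alpha-T-catenin, was dim (4.41 and 4.68) and differed by -0.27 (SE 0.15) on the log2 scale, STOX1 minus wild-type. Ccnb1, which encodes cyclin B1, differed by -0.027 (SE 0.28). None of the 3 passed the test over all features, with limma adjusted p of 0.676 for Stox2, 0.699 for Ctnna3 and 0.988 for Ccnb1.

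The comparison of STOX1 with wild-type pools asks which placental genes differ when STOX1 is overexpressed. At an unadjusted p under 0.01, the genes furthest above wild-type included several of myeloid immune cells. Fcgr4, an activating receptor for immunoglobulin G on myeloid cells, stood at 8.47 ± 0.19 in STOX1 pools and 6.04 ± 0.22 in wild-type pools (SD, n = 2 each), a 5.38-fold difference. Pilra, an inhibitory receptor of myeloid cells, was 3.24-fold higher (log2 difference 1.70, SE 0.18). Tlr8, an endosomal receptor for single-stranded RNA, stood at 6.03 in STOX1 and 3.94 in wild-type pools, the latter below the median of olfactory receptor genes in either wild-type pool (4.84 and 4.54), so its fold is not given. Klra2, of the Ly49 receptor family, was 4.57-fold higher (2.19, SE 0.39).

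The largest difference above wild-type at an unadjusted p under 0.01 belonged to Hrh1, the histamine H1 receptor, at 6.74 ± 0.73 in STOX1 pools and 3.34 ± 0.034 in wild-type pools. The wild-type level lies close to the lowest values on the arrays, 2.63 to 2.69, so its fold depends on how the dimmest signals were processed. Esrrg, the orphan nuclear receptor estrogen-related receptor gamma, stood at 6.39 ± 0.66 against 3.88 ± 0.42, and Spata17 at 5.55 against 3.74, with wild-type levels again under the olfactory receptor medians, so the same limit holds. Spata17, Lrriq3, Zfp444 and Cyp4f18, the last a cytochrome P450 that hydroxylates leukotriene B4, had log2 differences from 1.68 to 1.81. Among the 10 genes furthest below wild-type at the same level, Tes, which encodes the focal adhesion protein testin, was 6.75-fold lower (-2.75, SE 0.49). Sprr2e, a small proline-rich protein of epithelial surfaces, stood at 3.73 in STOX1 and 5.92 in wild-type pools, the former below the median of olfactory receptor genes in either STOX1 pool (4.20 and 4.30). The other 8 were olfactory receptor genes: Olfr638, Olfr127, Olfr1487, Olfr27, Olfr1480, Olfr1046, Olfr592 and Olfr745, with log2 differences from -2.98 to -2.28 and STOX1 levels from 3.09 to 5.06, so they too rest on dim signals.

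None of these genes passed the test. With limma and Benjamini-Hochberg adjustment over all 25631 features, 0 features had an adjusted p under 0.05, and the smallest adjusted p was 0.590. At an unadjusted p under 0.05 the same limma fit held 2040 features, 956 higher and 1084 lower in STOX1 pools, where 1282 would be expected by chance. Splitting the 4 arrays into the other possible pairs, each of a STOX1 and a wild-type pool, gave 734 and 1653 features. A plain equal-variance test of each feature also gave 0 after adjustment and 1865 unadjusted, with the opposite balance of 1038 higher and 827 lower. The limma balance turned the same way without the lower 50% of features, to 903 higher and 683 lower, so neither direction prevailed in all fits. In 10446 features, 40.8%, both STOX1 arrays lay on the same side of both wild-type arrays, against 33.3% by chance. Of these, 792 features differed at least 2-fold, 311 higher and 481 lower. In simulated arrays of the same size, limma recovered 0 of 50 features changed by 1 log2 unit, 1 of 50 changed by 2 units, 22 of 50 changed by 3 units and 34 of 50 changed by 4 units, so most single-gene differences of the sizes above would not be detected by this design.

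Among 44 gene lists fixed in advance, macrophage genes showed the largest shift of those that passed. The 15 measured macrophage genes were on average 1.51-fold higher in STOX1 pools (mean log2 difference 0.60, median 0.40), and 12 of the 15 lay above 0. In 9 of them both STOX1 arrays exceeded both wild-type arrays, where chance gives 2.5. C1qc and C1qa, subunits of the complement component C1q that macrophages make, were 2.48-fold (log2 1.31, SE 0.25) and 1.77-fold (0.82, SE 0.19) higher. Adgre1, the F4/80 antigen, was 2.75-fold higher (1.46, SE 0.34), and Lyz2, the macrophage lysozyme, 1.49-fold higher (0.57, SE 0.14).

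The 3 members below 0 were Cd163 (-0.20, SE 0.27) and Lyve1 (-0.20, SE 0.15), receptors carried by resident tissue macrophages, and Aif1 (-0.37, SE 0.28). The list rose in the camera test of limma with a preset correlation of 0.01 (adjusted p = 0.00297), but not with an estimated correlation (adjusted p = 0.776 with an estimated correlation). That adjusted value was shared by most lists, and the macrophage list's unadjusted camera p there was 0.0552. Its estimated correlation was -0.016, below the preset one, so a higher correlation is not why the call was lost. With an estimated correlation camera uses the 2 residual degrees of freedom, which the preset test does not, so the loss says little about this list. No single member passed over all features or adjusted over the list alone, where the smallest p was 0.0559. The median difference was 0.56 against wild-type pool 1 taken alone and 0.53 against wild-type pool 2.

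**Figure D1:**
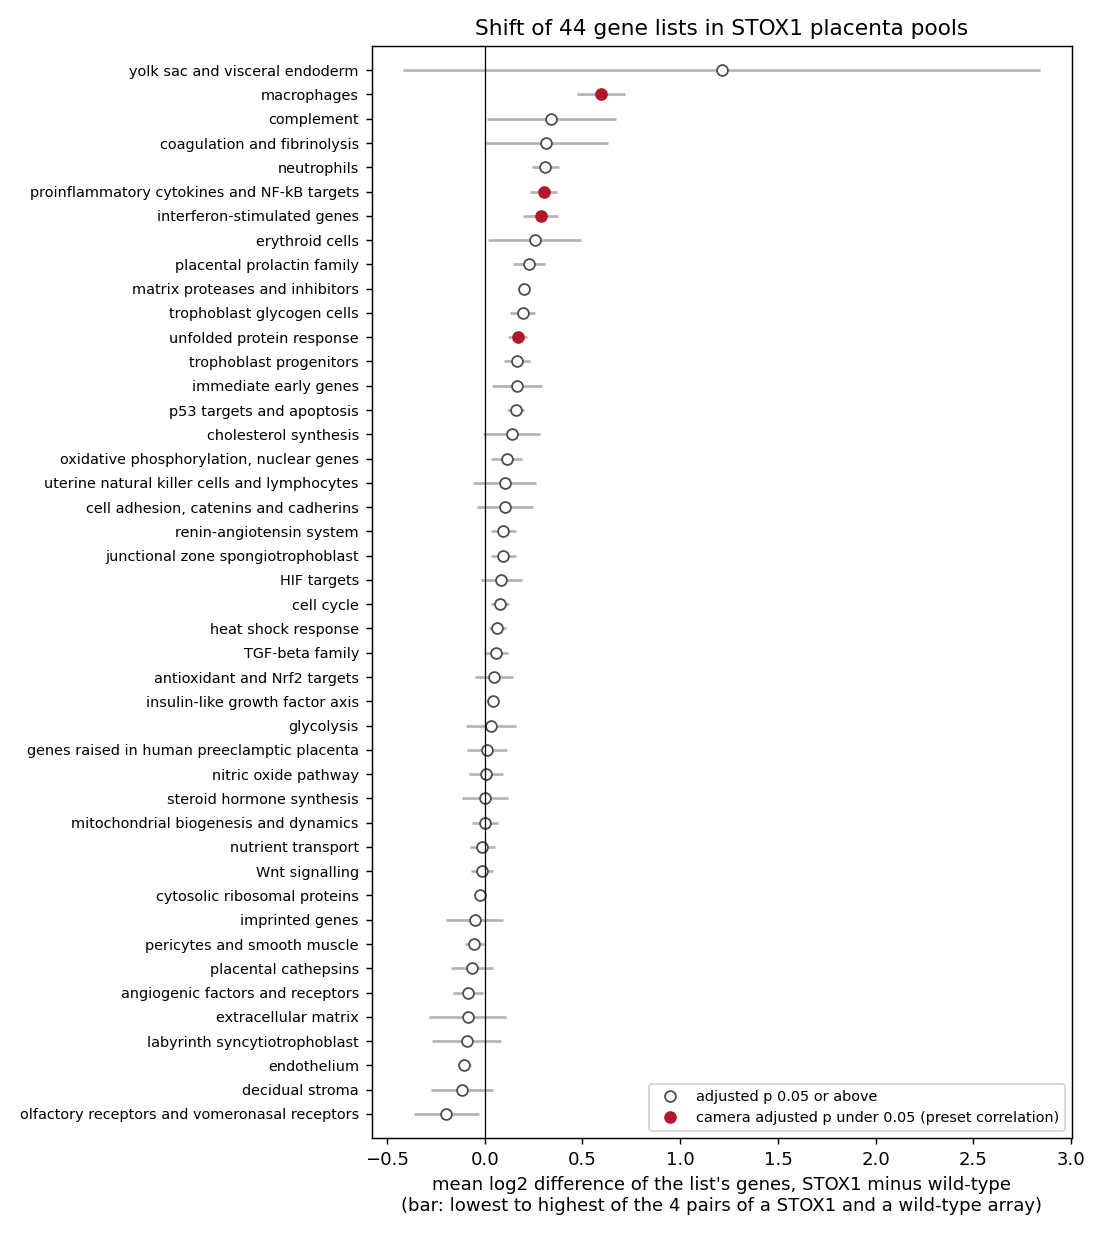
Mean log2 difference of the measured genes of each of 44 lists, STOX1 minus wild-type (horizontal axis). Each circle is the mean over 2 arrays per group, the bar runs from the lowest to the highest of the 4 pairs of a STOX1 and a wild-type array, and filled circles mark the 4 lists with a camera adjusted p under 0.05 at the preset correlation. The 4 marked lists lie between 0.17 and 0.60, and the yolk sac list has the widest bar, from -0.42 to 2.84.

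Interferon-stimulated genes were also higher as a list. The 28 measured genes were on average 1.22-fold higher (mean log2 difference 0.29, median 0.26), 26 of 28 lay above 0, and in 17 of them both STOX1 arrays exceeded both wild-type arrays, where chance gives 4.67. Igtp, an interferon-inducible GTPase, was 1.73-fold higher (0.79, SE 0.17), and Oas3, an antiviral oligoadenylate synthetase, stood at 12.63 in STOX1 and 12.01 in wild-type pools (difference 0.62, SE 0.14). Irf7, the transcription factor that amplifies type I interferon, differed by 0.62 (SE 0.18), and Usp18, which removes ISG15 from proteins, by 0.52 (SE 0.14). The members below 0 were Xaf1 (-0.40, SE 0.15) and Oas2 (-0.075, SE 0.26). The camera adjusted p was 0.000257 at the preset correlation (adjusted p = 0.776 with an estimated correlation). The estimated correlation was 0.028, and the unadjusted camera p with it was 0.0616. No member passed over all features or adjusted over the list alone. The interferon list's median difference was 0.39 against wild-type pool 1 taken alone and 0.20 against wild-type pool 2. The macrophage list, which shares 0 genes with this list, was higher in the same pools by 0.60 on average.

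Proinflammatory cytokines and NF-kB targets were the third list to pass. Of 28 measured genes, 24 lay above 0, with a mean log2 difference of 0.30 and a median of 0.20, and 11 had both STOX1 arrays above both wild-type arrays. Il1b and Tnf, cytokines made mainly by myeloid cells, were 3.30-fold (1.72, SE 0.43) and 2.94-fold (1.56, SE 0.35) higher. Sele, the endothelial adhesion molecule E-selectin, stood at 10.72 ± 0.082 and 9.99 ± 0.028 (SD, n = 2 each), and Cxcl1, a chemokine that attracts neutrophils, was 1.41-fold higher (0.50, SE 0.14). The camera adjusted p was 0.0215 (adjusted p = 0.776 with an estimated correlation), and no member passed over all features or adjusted over the list alone. Without wild-type pool 1 the list's mean was 0.28 (adjusted p = 0.132), and without STOX1 pool 1 it was 0.25 (adjusted p = 0.101). Its median was 0.31 against wild-type pool 1 taken alone and 0.15 against wild-type pool 2. The list shares 1 gene with the interferon list and 0 with the macrophage list, which was higher in the same pools.

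The unfolded protein response, the set of chaperones and folding enzymes induced by stress in the endoplasmic reticulum, had the smallest shift of the lists that passed. Its 25 measured genes were higher by 0.17 on average (median 0.19), 23 of 25 lay above 0, and 16 had both STOX1 arrays above both wild-type arrays, where chance gives 4.17. Hyou1, an endoplasmic reticulum chaperone, differed by 0.36 (SE 0.14), Creld2 by 0.29 (SE 0.14), and the disulfide isomerases Pdia6 and Pdia4 by 0.44 (SE 0.22) and 0.24 (SE 0.14). Hspa5, the main chaperone of this response, did not share the direction (-0.052, SE 0.14). Macrophage genes were higher in the same pools by 0.60 on average, and the prolactin family, whose products are secreted, by 0.23. The camera adjusted p was 0.0265 (adjusted p = 0.776 with an estimated correlation), and no member passed over all features or adjusted over the list alone. The list did not pass with the replicate block (mean 0.17, adjusted p = 0.0738), without STOX1 pool 1 (0.17, adjusted p = 0.0594) and without STOX1 pool 2 (0.17, adjusted p = 0.272), where its mean stayed about as large, nor without wild-type pool 1 (0.12, adjusted p = 0.230).

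The other immune lists did not pass in the main test. Neutrophil genes were higher by 0.31 on average over 13 genes (camera adjusted p = 0.0743), with the proteases Mmp8 and Mmp9 at 1.97-fold (0.98, SE 0.16) and 1.92-fold (0.94, SE 0.31). Complement genes were higher by 0.34 over 20 genes (adjusted p = 0.0981). The complement list shares 3 genes with the macrophage list and also holds Cfi, which was low in wild-type pool 2 alone (7.63, against 12.04 to 13.02 in the other 3 arrays). The complement list stood at 0.59 without wild-type pool 1 (adjusted p = 0.00782) and at 0.086 without wild-type pool 2 (adjusted p = 0.733; adjusted p = 0.776 with all arrays and an estimated correlation). Genes of uterine natural killer cells and lymphocytes differed by 0.10 over 21 genes (adjusted p = 0.467), by 0.00066 without wild-type pool 1 and by 0.21 without wild-type pool 2. Among them, Klrd1 (CD94) differed by 0.91 (SE 0.20), with a wild-type level of 3.83 under the olfactory receptor medians, and Il2rb, the interleukin 2 receptor beta chain, by 0.66 (SE 0.17).

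Trophoblast lineages were compared through their marker lists, none of which passed. The placental prolactin family, hormones of trophoblast giant cells and spongiotrophoblast, was higher by 0.23 on average (19 of 24 genes above 0, camera adjusted p = 0.0523). Prl3d1 and Prl3d3, placental lactogen I genes of giant cells, were 1.69-fold (0.76, SE 0.26) and 1.76-fold (0.81, SE 0.29) higher. The list stood at 0.29 without STOX1 pool 1 (adjusted p = 0.0250) and at 0.16 without STOX1 pool 2 (adjusted p = 0.272), and it passed after quantile normalization (0.23, adjusted p = 0.0433; adjusted p = 0.776 with an estimated correlation). Junctional zone spongiotrophoblast genes differed by 0.095 (adjusted p = 0.192), with Prl3a1 at 0.33 (SE 0.15) and Ceacam9 at 0.22 (SE 0.15), and by 0.059 to 0.13 with an array left out. Trophoblast glycogen cell genes differed by 0.19 (adjusted p = 0.141), trophoblast progenitor genes by 0.17 (0.192) and placental cathepsins by -0.065 (0.526). Labyrinth syncytiotrophoblast genes differed by -0.092 (adjusted p = 0.256), by -0.20 without wild-type pool 1 and by 0.019 without wild-type pool 2, so the sign of the mean depended on the wild-type pool kept. The cathepsin mean likewise turned to 0.034 without STOX1 pool 2. Among the labyrinth genes Gcm1, the transcription factor that drives syncytiotrophoblast formation, differed by -0.36 (SE 0.15) and Egfr by 0.29 (SE 0.14).

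Vascular and pre-eclampsia related lists did not pass in the main test, though the endothelial list did in alternatives that leave out dim features. The receptor gene Flt1 stood at 10.35 ± 0.042 in STOX1 pools and 10.15 ± 0.039 in wild-type pools (SD, n = 2 each), a 1.15-fold difference with a limma adjusted p of 0.742. It had 1 feature, so its soluble form was not measured separately. Eng (endoglin) differed by -0.076 (SE 0.17), Pgf (placental growth factor) by 0.16 (SE 0.27), Vegfa by -0.18 (SE 0.15) and Nos3, the endothelial nitric oxide synthase, by -0.36 (SE 0.21). Lep (leptin), at 3.61 and 3.41 below the olfactory receptor medians of both groups, differed by 0.20 (SE 0.29) and Hif1a by 0.081 (SE 0.14). Genes raised in human preeclamptic placenta differed by 0.014 on average over 15 genes (camera adjusted p = 0.890), by -0.043 without wild-type pool 1 and by 0.070 without wild-type pool 2.

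Angiogenic factors and receptors differed by -0.087 over 22 genes (camera adjusted p = 0.180), by -0.14 without wild-type pool 1 and by -0.031 without wild-type pool 2, with Angpt1 at 0.44 (SE 0.15) and Edn1, endothelin 1, at -0.54 (SE 0.21). Endothelial genes differed by -0.10 (5 of 20 above 0, adjusted p = 0.0743), with Tek at -0.38 (SE 0.15) and Ramp2 at -0.42 (SE 0.16). The endothelial list passed without the lowest 25% of features (mean -0.10, adjusted p = 0.0438) and without the lower 50% (mean -0.16, adjusted p = 0.00766), but not with an estimated correlation over all features (adjusted p = 0.776). Pericyte and smooth muscle genes differed by -0.052 (adjusted p = 0.518), and by -0.088 to -0.016 with an array left out. In the nitric oxide pathway Gch1, which makes the synthase cofactor tetrahydrobiopterin, was 1.78-fold higher (0.83, SE 0.18) and Prkg1, the cGMP-dependent kinase, 1.51-fold lower (-0.60, SE 0.14). That list's mean was 0.0090, its median -0.094 and its test direction down (adjusted p = 0.674), and the mean ran from -0.054 to 0.072 with an array left out. The renin-angiotensin list likewise had a mean of 0.096 with a median of -0.044 and a test direction of down (0.753), and the mean ran from 0.034 to 0.16. Coagulation and fibrinolysis genes differed by 0.31 (adjusted p = 0.132), by 0.57 without wild-type pool 1 (adjusted p = 0.00870) and by 0.052 without wild-type pool 2 (adjusted p = 0.861; adjusted p = 0.776 with all arrays and an estimated correlation). The coagulation list also holds F2 and Plg, which were low in wild-type pool 2 alone (8.20 and 5.81, against at least 10.89 and 7.83 elsewhere). Of the coagulation genes, 1 passed adjusted over the list alone and 0 over all features. The adjustment over a list was made in each of 44 lists, without correcting for their number. That gene was F5, coagulation factor V, 2.51-fold higher in STOX1 pools (1.33, SE 0.18, limma p adjusted over the list 0.0462).

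The other metabolic and stress lists did not pass the main camera test. Nuclear genes of oxidative phosphorylation differed by 0.11 on average, with both STOX1 arrays above both wild-type arrays in 27 of 54 genes where chance gives 9 (adjusted p = 0.0831). The mean was 0.046 without wild-type pool 1 (adjusted p = 0.540) and 0.18 without wild-type pool 2 (adjusted p = 0.0642). Cox6b1, a cytochrome c oxidase subunit, differed by 0.52 (SE 0.18) and Atp5d, an ATP synthase subunit, by 0.38 (SE 0.16). Antioxidant and Nrf2 target genes differed by 0.049 (adjusted p = 0.603), by 0.12 without wild-type pool 1 and by -0.021 without wild-type pool 2. Among them Prdx6 differed by -0.85 (SE 0.24) and Keap1 by 0.35 (SE 0.14). The Prdx6 feature was rather dim, at 5.12 in STOX1 and 5.97 in wild-type pools, under the array medians. HIF targets differed by 0.084 (0.467), by 0.029 without wild-type pool 1 and by 0.14 without wild-type pool 2, with Pfkfb4 at 0.80 (SE 0.17) and the collagen prolyl hydroxylase P4ha2 at 0.58 (SE 0.16). Glycolysis genes differed by 0.034 (0.703), by -0.054 without wild-type pool 1 and by 0.12 without wild-type pool 2, heat shock genes by 0.065 (0.674, from 0.037 to 0.093 with an array left out) and cholesterol synthesis genes by 0.14 (0.0831). Cholesterol synthesis stood at 0.27 without wild-type pool 1 (adjusted p = 0.00870), at 0.0097 without wild-type pool 2 (adjusted p = 0.932) and at 0.24 without the lower 50% of features (adjusted p = 0.0295; adjusted p = 0.776 with all arrays and an estimated correlation).

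Mitochondrial biogenesis and steroid hormone synthesis had means of 0.0023 and 0.0034 and medians of 0.065 and 0.025, while the camera test pointed down for both (adjusted p = 0.703 each). With an array left out these means ran from -0.062 to 0.067 and from -0.11 to 0.11. p53 targets and apoptosis genes differed by 0.16 (0.0743), with the executioner caspase Casp3 at 0.51 (SE 0.18) and Zmat3 at 0.35 (SE 0.13). Immediate early genes, which also respond to handling of tissue, differed by 0.17 (0.0670), by 0.28 without wild-type pool 2 (adjusted p = 0.0158) and by 0.050 without wild-type pool 1 (adjusted p = 0.540; adjusted p = 0.776 with all arrays and an estimated correlation).

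Growth, matrix and signalling lists did not pass either. Imprinted genes differed by -0.050 over 34 genes (camera adjusted p = 0.0523), with Rtl1, a retrotransposon-derived gene of the placental vessels, at -0.57 (SE 0.14) and Plagl1 at -0.43 (SE 0.15). The imprinted list stood at -0.14 without wild-type pool 2 (adjusted p = 0.0464), and its mean lay above 0 without wild-type pool 1 (0.041, adjusted p = 0.426) and without STOX1 pool 2 (0.0043, adjusted p = 0.272), while the test pointed down in all 3. With all arrays the list passed after quantile normalization (-0.058, adjusted p = 0.0426), without the lowest 25% of features (-0.063, adjusted p = 0.0163), without the lower 50% (-0.062, adjusted p = 0.00304) and with the mean of a gene's features (-0.058, adjusted p = 0.0462), but not with an estimated correlation (adjusted p = 0.776). Extracellular matrix genes differed by -0.088 (0.328), but by -0.27 without wild-type pool 2 (adjusted p = 0.00780) and by 0.091 without wild-type pool 1 (0.441; adjusted p = 0.804 with all arrays and an estimated correlation), so the sign of the mean depended on the wild-type pool kept. Decidual stroma genes differed by -0.11 (0.0981), by -0.22 without wild-type pool 1 (adjusted p = 0.0377), by -0.015 without wild-type pool 2 (0.739) and by -0.055 without STOX1 pool 2 (0.521; adjusted p = 0.776 with all arrays and an estimated correlation). Matrix proteases and inhibitors differed by 0.20 (0.127), adhesion genes by 0.10 (0.603), nutrient transport by -0.011 (0.525), Wnt signalling by -0.014 (0.612), the TGF-beta family by 0.059 (0.703), cell cycle genes by 0.080 (0.802) and cytosolic ribosomal proteins by -0.024 (0.127). The ribosomal list passed without the lower 50% of features (-0.027, adjusted p = 0.0124; adjusted p = 0.776 with an estimated correlation over all features), and its mean ran from -0.041 to -0.0064 with an array left out. The nutrient transport mean ran from -0.070 to 0.048, the Wnt mean from -0.046 to 0.017 and the TGF-beta mean from 0.010 to 0.11, and the adhesion mean was -0.036 without wild-type pool 2 and 0.24 without wild-type pool 1. The insulin-like growth factor list had a mean of 0.041, a median of -0.0054 and a test direction of down (0.703), with means from 0.021 to 0.062 with an array left out. Erythroid genes differed by 0.26 (0.218), with Ermap at 0.91 (SE 0.14) and Epb42 at 1.04 (SE 0.23), and by 0.47 without STOX1 pool 1 (adjusted p = 0.00405). Without STOX1 pool 2 the erythroid difference was 0.045 (adjusted p = 0.984; adjusted p = 0.776 with all arrays and an estimated correlation). Over the 44 lists, leaving out an array turned the sign of the mean at least once in 14, and turned it or moved it by over 1.5 times in 32.

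Wild-type pool 2 stood apart from the other 3 arrays in yolk sac and Y-linked genes. All 18 measured genes of yolk sac and visceral endoderm were lowest in that pool, by a median of -2.55 on the log2 scale against the mean of the other 3 arrays. Alb (albumin) stood at 7.04 there, against 13.68 in wild-type pool 1 and 12.62 and 12.26 in the STOX1 pools. The Y-linked genes Eif2s3y and Ddx3y stood at 3.40 and 2.93 in wild-type pool 2, against at least 10.49 and 9.93 in the other 3 arrays, and Kdm5d at 4.41 against at least 7.47. Uty, also Y-linked, did not follow, with 8.34 in wild-type pool 2 and 8.27 to 8.90 elsewhere.

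The yolk sac list accordingly had a mean difference of 1.21 between the groups (camera adjusted p = 0.0523), which was 2.83 without wild-type pool 1 (adjusted p = 5.65e-23) and -0.41 without wild-type pool 2 (adjusted p = 0.000144), both at the preset correlation. Its adjusted p was 0.0141 with the replicate block, 0.0436 after quantile normalization and 0.0412 after median centring, but 0.776 with an estimated correlation, which at 0.868 was the highest of the 44 lists. Apoa2 (1.90, SE 1.25) carried the low value of that pool, while Ahsg, fetuin A, differed by 0.89 (SE 0.27). The placental prolactin family showed no such gap in wild-type pool 2 (median -0.048). In all, 89 genes lay at least 4-fold below the other 3 arrays in wild-type pool 2, against 0 in wild-type pool 1, 8 in STOX1 pool 1 and 0 in STOX1 pool 2.

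**Figure D2:**
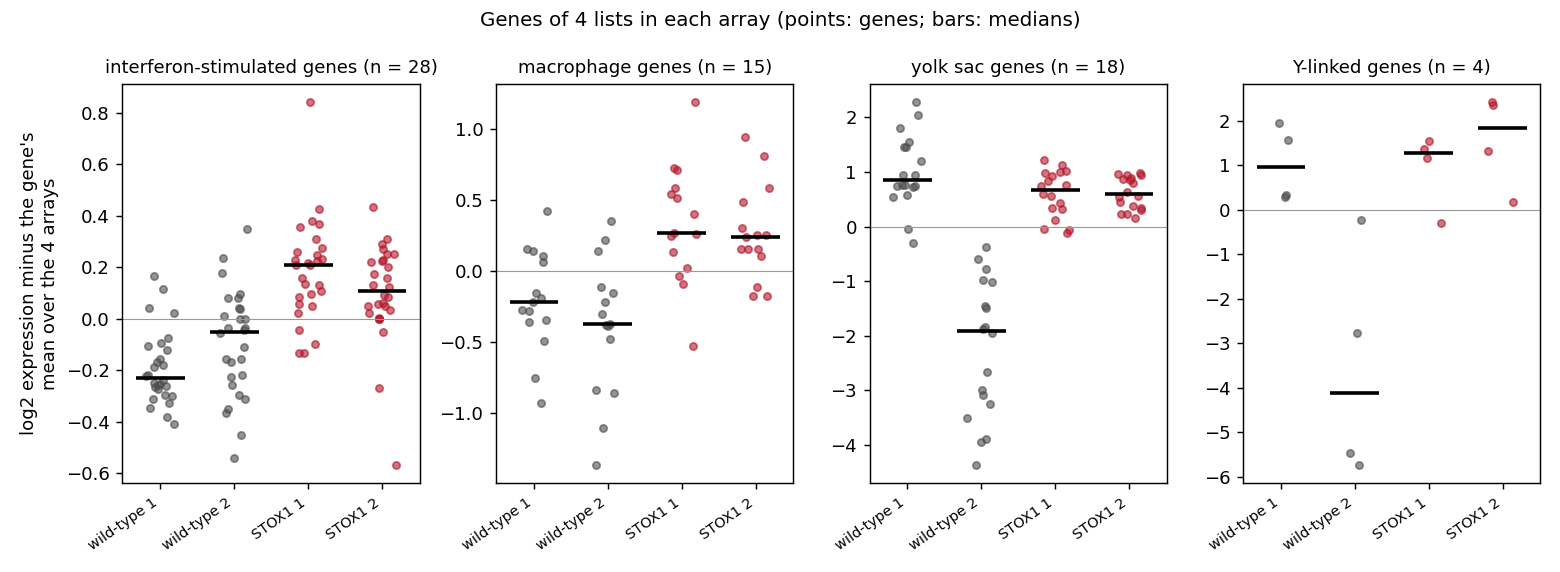
Log2 expression of each gene minus its mean over the 4 arrays (vertical axis, its range differing between panels) in each of the 4 arrays, for interferon-stimulated, macrophage, yolk sac and Y-linked genes. Points are genes, bars are medians, grey marks wild-type and red marks STOX1 pools. Interferon-stimulated and macrophage medians are higher in both STOX1 pools, and the 18 yolk sac genes are lowest in wild-type pool 2.

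Olfactory receptor genes, which serve odour detection in the nose, had a median log2 difference of -0.30 over 1064 genes, and 76.9% of them lay below 0. Among 232 symbol families tested with camera after the data were seen, this family had an adjusted p of 3.39e-16 at the preset correlation (adjusted p = 0.991 with an estimated correlation). The type 1 vomeronasal receptors (Vmn1r, adjusted p = 0.0163) and the late cornified envelope proteins (Lce, adjusted p = 0.0318) also passed, both lower in STOX1 pools, and neither did with an estimated correlation (adjusted p = 0.991 each). Both STOX1 arrays lay below both wild-type arrays in 39.1% of the genes, where chance gives 16.7%. Their median level was 4.84 and 4.54 in the wild-type pools and 4.20 and 4.30 in the STOX1 pools, far under the array medians. The direction was also down after quantile normalization (-0.26) and median centring (-0.31), and the median was -0.18 without wild-type pool 1. The list of 23 olfactory and vomeronasal receptors fixed in advance differed by -0.20 and did not pass (camera adjusted p = 0.127), with -0.088 without STOX1 pool 1 and -0.30 without STOX1 pool 2, and the family of 1064 genes was looked at only after its members appeared among the genes furthest below wild-type.

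**Figure D3:**
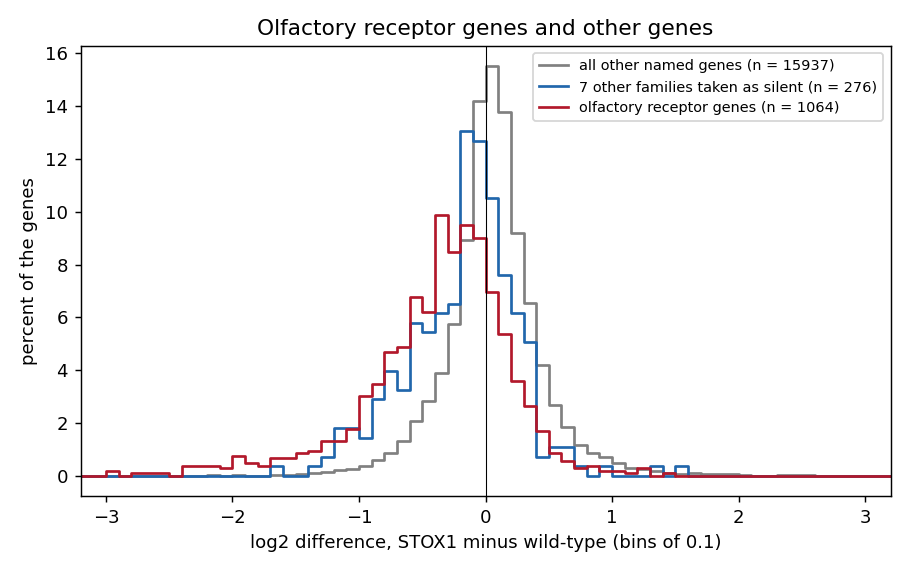
Distribution of log2 differences, STOX1 minus wild-type (horizontal axis, bins of 0.1), as a percent of the genes of each set (vertical axis), for 1064 olfactory receptor genes, 276 genes of 7 other families taken as silent in placenta and the other 15937 named genes. The medians are -0.30, -0.13 and 0.053.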

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

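The other backgrounds, the crossed block and the test of named genes alone were chosen only after the results were seen. The count of features with a limma adjusted p under 0.05 was 0 in each of the 14 alternatives, with smallest adjusted p from 0.223 to 0.976. The count of lists called by camera, 4 as reported, was 7 after quantile normalization, 8 without the lower 50% of features, 0 with an estimated correlation, 0 with fry and 12 with all features as background. Leaving out each array in turn gave 3 to 8 lists. Fewer features, fewer arrays and, for the estimated correlation, a p-value at 2 residual degrees of freedom are part of the respective alternatives. The cause of the other differences was not tested. The interferon and macrophage lists were called in 13 of 15 alternatives each, with adjusted p from 4.21e-05 and 0.000586 up to 0.776, and in all 4 that leave out an array. The cytokine list was called in 11 and the unfolded protein response in 9. Imprinted genes, not called as reported, were called down after quantile normalization, without the lowest 25% or the lower 50% of features, with the mean of a gene's features, with no olfactory or vomeronasal genes in the background and without wild-type pool 2, with adjusted p from 0.00304 to 0.0464. Endothelial genes were called down without the lowest 25% (0.0438) and the lower 50% of features (0.00766). With all features as background, oxidative phosphorylation (0.0269), p53 targets and apoptosis (0.0269) and immediate early genes (0.0257) were called higher. Neutrophil (0.0309), complement (0.0385), cholesterol synthesis (0.0333), prolactin family (0.0152) and yolk sac genes (0.0152) were called higher there too. None of these lists passed camera with an estimated correlation (adjusted p = 0.776 each). The yolk sac list reversed without wild-type pool 2, to -0.41, the array in which those genes were lowest, and its range over the arrays left out was -0.41 to 2.83. With the replicate block 0 features and 4 lists were called, the yolk sac list taking the place of the unfolded protein response, and it changed no other call. The pool numbers are not shown to pair the samples: the deviations of same-numbered pools correlated at -0.133 across features. A crossed block gave 0 features and 6 lists. Without a background measure, differences among the dimmest features are the least certain.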

Other observations

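The tests of a poor array, of male placentas, of wild-type pool 2 or a single wild-type pool setting a shift, and of olfactory receptors against dim or silent genes were chosen only after the result was seen, as were the patterns themselves.

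Further myeloid genes outside the fixed lists were higher in the STOX1 pools, by values seen before they were chosen. Fcgr2b, the inhibitory receptor for immunoglobulin G, stood at 10.34 against 9.13 in wild-type pools (2.31-fold, log2 1.21, SE 0.14). Cybb, the catalytic subunit of the phagocyte oxidase, was 2.66-fold higher (1.41, SE 0.17), and Ccr2, a chemokine receptor of recruited monocytes, 2.95-fold higher (1.56, SE 0.21). Itgax, the integrin CD11c, was 2.00-fold higher (1.00, SE 0.14). None passed limma's adjustment over all features (adjusted p = 0.590 each). Among genes further below wild-type, Acat1, a mitochondrial enzyme of ketone metabolism, stood at 6.52 in STOX1 and 7.93 in wild-type pools (log2 -1.41, SE 0.15), and Pthlh, parathyroid hormone-related protein, differed by -1.49 (SE 0.22).

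To test the hypothesis that myeloid genes as a class are higher, 30 myeloid genes were listed before their values were seen, 29 of them measured and 0 of them in another fixed list. Their mean difference was 0.66, 1.58-fold, 25 of 29 lay above 0, and in 22 both STOX1 arrays exceeded both wild-type arrays. Ctss, cathepsin S, differed by 0.94 (SE 0.14), Ncf1, a phagocyte oxidase subunit, by 1.03 (SE 0.17), and Cd52 by 1.16 (SE 0.19), while 4 lay below 0: Trem2 (-0.030, SE 0.22), Coro1a (-0.062, SE 0.48) and the oxidase subunits Ncf2 (-0.11, SE 0.20) and Ncf4 (-0.12, SE 0.39). The median of 0.67 lay at percentile 100 of random lists matched on mean expression, whose own median was 0.055. Those lists draw genes independently, and the arrays are the same 4 in which macrophage genes were already higher. A chance difference between pools in genes that move together therefore stays open here too. The camera p was 4.99e-12 at the preset correlation and 0.0318 with an estimated correlation, as a single test chosen after the macrophage list. The median was 0.63 against wild-type pool 1 and 0.60 against wild-type pool 2. These values could come from more myeloid cells, or more expression per cell, in these STOX1 pools, which bulk arrays do not separate. Some of the listed genes, Cd52 among them, are also expressed by lymphocytes, so a rise of other leukocytes is not told apart either.

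Interferon-stimulated and macrophage genes were the lists that passed camera at the preset correlation whichever array was left out, but neither passed with an estimated correlation (adjusted p = 0.776 each) or with fry (0.259 each). In the same preset test, that wild-type pool 2 alone sets the shift is argued against by the larger of their adjusted p without it, 0.0158. A shift of all genes of that brightness is argued against by their medians, the lower of them at percentile 99.9 of matched random lists. A chance difference between pools with genes that move together stays open. The real split called 4 lists and the highest of the other splits 2, and with 3 splits in all no share under 0.05 can be reached. The smallest camera adjusted p of any list was 6.66e-06 and 2.83e-06 in the other splits, against 0.000257 in the real one. Both other splits called the yolk sac list, and neither called the interferon or macrophage list. STOX1 overexpression, litter, dissection and the sex of the placentas in the pools may each have contributed, and the design does not separate them.

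Yolk sac and Y-linked genes were low in wild-type pool 2 alone. A poor array or RNA sample as the whole cause is argued against: of 1714 other genes as bright in the other 3 arrays, 7 (0.41%) lay at least 4-fold lower in that pool than the mean of the other 3, against 14 of the 22 yolk sac and Y-linked genes. Less yolk sac tissue in that pool was tested with a second list written before its values were seen: 19 of 20 genes were measured, 15 were lowest there, and the median was -2.36, with Gc at 6.30 against at least 11.79 and Ambp at 6.86 against at least 10.44 in the other arrays. Few or no male placentas in that pool stay open: the Y-linked genes, with a median of -5.50, prompted the explanation and cannot test it. Eif2s3y and Ddx3y stood there at 3.40 and 2.93, near that array's lowest value of 2.68. Uty did not follow, but against its mean over the 4 arrays it was lower in STOX1 pool 1 (-0.29) than in wild-type pool 2 (-0.22). Ddx3y and Eif2s3y were high in STOX1 pool 1, so Uty does not weigh against the explanation. Less yolk sac tissue may account for the yolk sac part only, the labels describe a dissection away from fetal membranes, and the sex of the placentas is not given.

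Olfactory receptor genes had lower medians in both STOX1 pools than in either wild-type pool. A shift of all dim named genes is argued against. The median of -0.30 lay at percentile 0 of lists matched on mean expression, whose own median was 0.031. Those lists were drawn from named genes outside the olfactory and silent families. The 7851 unnamed features were not in them, so for those features a shift stays open. That a single wild-type pool sets the shift is argued against by the smaller of the differences, -0.18 against wild-type pool 2. Background signal that also moves other gene families silent in placenta stays a candidate explanation: the median of 276 genes of vomeronasal, trace amine and taste receptors, keratin-associated proteins, late cornified envelope proteins and beta-defensins was -0.13, also at percentile 0, -0.084 after quantile normalization and -0.071 without wild-type pool 1. No separate biological explanation was tested.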
